A study of Mus musculus with 10 samples.

How the data were processed

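Polyadenylated RNA was measured in 10 libraries of mouse morulae of the strain combination BDF1 x PWK, per the labels. The single-embryo set held 6 libraries of 1 female embryo each, 3 wild type (replicates 1 to 3) and 3 Jarid2 knockout (replicates 1, 3 and 4). A replicate 2 of the knockout single embryos was not analysed here. The pooled set held 4 libraries of about 20 embryos each, 2 control and 2 knockout, and the sex of these embryos is not given in the sources used here. Per the labels' protocols, complementary DNA was made with the SMART-Seq v4 chemistry, libraries were built with Nextera XT, and single-end reads of 75 bases were taken on an Illumina NextSeq instrument.

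The deposited table gives whole-number read counts per gene for each library, without normalization. The tools and assembly named in the submitters' processing notes are fastp 0.21.0, STAR 2.7.6a, RSEM 1.3.1 and mm10. Which of them made the counts, with which annotation, and how strand and reads with several matches were handled are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart. Of 91 named genes, 27 overlap another gene of the table. The values of Xist (with Tsix), Sycp3 (with Chpt1), H13 (with Mcts2), Spen (with Zbtb17), Aurka (with Cstf1), Cdc20 (with Elovl1), Sp110 (with Sp140), Hspa5 (with Rabepk), Arg2 (with Vti1b), Zfp750 (with Tbcd) and Col4a1 with Col4a2 are uncertain for this reason. Those of Tuba3a, Xlr3a, Tdpoz2, Obox6, Esp24 and the ribosomal protein genes are uncertain because near-identical copies or pseudogenes can share reads.

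The table held 35976 genes, of which 33475 (93.05%) matched a symbol or synonym of the RefSeq gene table for GRCm38.p6, the assembly that mm10 stands for, from which coordinates were taken. A spreadsheet had turned 27 gene names into dates, and these held 0.13% to 0.15% of each library's counts; they stayed in the fits under the names in the table. Genes of the mitochondrial genome had 0 counts in every library and were not tested. Total counts were 14830332 to 18696312 in the single-embryo libraries and 41003216 to 49861963 in the pools. Reads carried no molecular identifiers, so counts are not independent molecules. No pair of libraries of a group held near-identical counts (chi-square per gene 45.6 to 80.1). The labels describe the single-embryo libraries as separate embryos. They do not say whether the pools came from separate litters, so p-values in the pools measure the spread between these pools, which may be technical.

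Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given, libraries were scaled by TMM (factors 0.925 to 1.08), and groups were compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 5%. Each set was fitted by itself. The difference between the knockout effects of the sets and their average were fitted over all 10 libraries with set as a term. All p-values are two-sided. Standard errors of log2 changes were taken from the change and its F value, and none is given for a gene with 0 counts in a whole group. CPM, counts scaled to a common library total, were computed from library totals. Fold changes carry a prior count of 0.125, and principal components used log2(CPM + 1).

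On simulated counts drawn from the means and library sizes of each set, with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 28% and 91% in the single-embryo design over 13173 genes, with 7 false calls (5.56% of its calls). In the pooled design it recovered 79% and 100% over 15802 genes, with 15 false calls (7.73%). The shares recovered cover only the genes drawn as changed, not all genes of each run. Recovery among genes with low counts was not measured separately and may be lower.

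The comparisons, tests, 30 gene lists (972 entries, 967 matched) and the rule for named genes were fixed before the data were examined. The rule takes, per set and direction, the 8 genes with the largest log2 change among those past 5% with a mean of at least 10 CPM and no overlap between groups, leaving out predicted genes and pseudogenes. Where none passed, it takes the 3 genes with the smallest p in that direction. It adds up to 3 members with the smallest p from each list with a call, and Jarid2, Xist, Ezh2, Eed, Suz12, Gab1, Sfmbt2, Slc38a4, Jade1 and Smoc1. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over lists, and also by camera with an estimated correlation and by fry. X-linked genes were compared with all others by camera, and the X-linked share of counts by an exact permutation test.

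Alternatives were other scalings (DESeq2 size factors, upper quartile, none), DESeq2 1.42.0, limma-voom, other filters on low counts, robust fitting, a 2-fold minimum, all 10 libraries in one fit, the replicate number as a block, and leaving out each library in turn. A correction of each library for transcript length and GC content, by splines with 5 degrees of freedom over GENCODE M21 transcripts, was added after the data were seen; 93% of tested genes had a length. Also chosen after the data were seen was a division of coding genes by the longest annotated protein: those with a stretch of 19 residues of mean Kyte-Doolittle hydropathy of at least 1.6, as membrane-spanning segments and signal peptides have, and those without. Intervals of medians are 95% bootstrap intervals over 2000 resamples of genes; they treat genes as independent and do not cover the spread between embryos. Tables and plots were made with Python 3.11.15.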

Results

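RNA of mouse morulae with and without Jarid2, a cofactor of the Polycomb complex PRC2, was sequenced as single female embryos (3 wild type, 3 knockout) and as pools of about 20 embryos (2 control, 2 knockout). The series compares knockout with control morulae. Total counts were 14830332, 17534188 and 17389519 in wild-type single embryos 1 to 3, and 18015186, 18696312 and 18071881 in knockout single embryos 1, 3 and 4. Control pools 1 and 2 held 42906533 and 47458704 counts, and knockout pools 1 and 2 held 49861963 and 41003216. The 10 most abundant genes of a library took 5.09% to 6.16% of its counts.

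The wild-type single embryos stood apart from the other libraries on the first principal component but not on the second. On the second, with 15.3% of the variance, wild-type replicate 2 (34.48) lay by knockout replicates 3 (33.24) and 4 (38.42), far from wild-type replicate 1 (-31.90). Wild-type replicate 2 correlated at 0.959 both with knockout replicate 3 and with wild-type replicate 3. On the first principal component, with 37.9% of the variance, they lay at 41.33 to 77.51, the knockout single embryos at -41.67 to 11.82, and the pools of both genotypes at -39.21 to -17.56. Across genes, which are not independent replicates, log2(CPM + 1) correlated with the pools at 0.960 to 0.972 for knockout single embryos and at 0.926 to 0.958 for wild-type ones. The labels give no batch by which to divide the libraries.

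**Figure D1:**
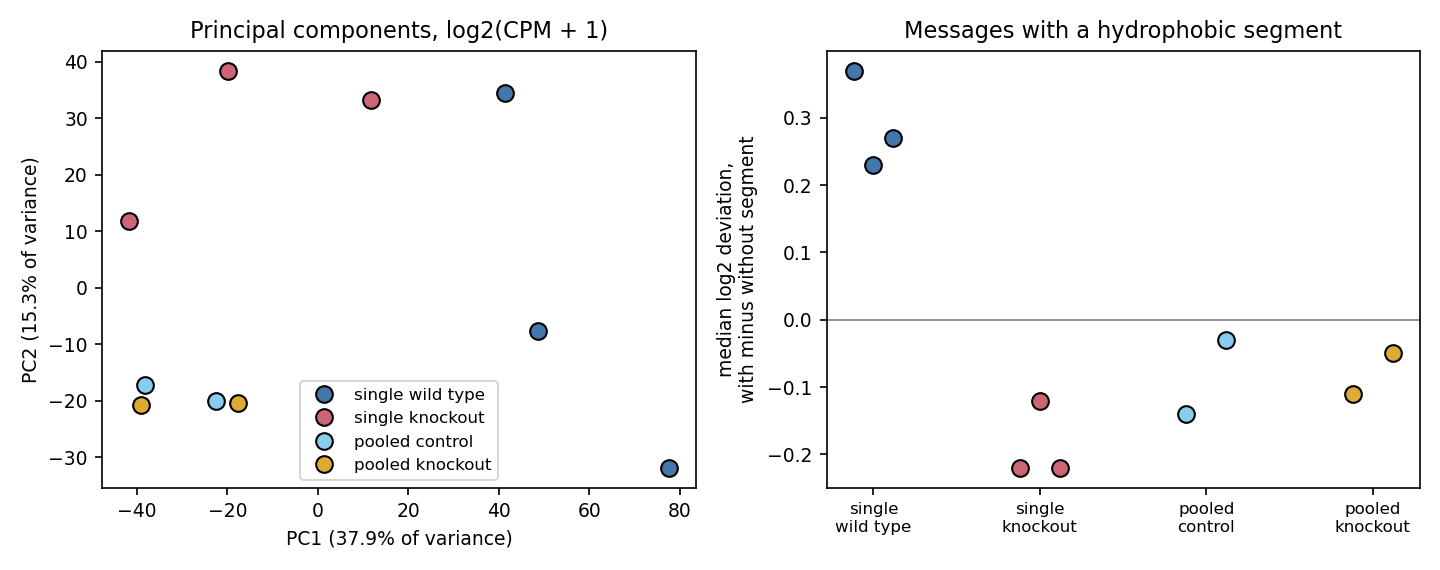
Left, principal components of log2(CPM + 1) for the 10 libraries, coloured by group; the wild-type single embryos lie at 41.33 or higher on the first. Right, for each library, the median log2 deviation from the mean of all libraries for genes with a hydrophobic protein segment minus that for genes without one; wild-type single embryos lie at 0.23 to 0.37 and all others at -0.22 to -0.03.

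Jarid2 (chromosome 13, 44730774 to 44921643) was lower in each knockout library than in each control library of its set. In wild-type single embryos it had 580.3, 686.0 and 775.6 CPM, against 156.1, 318.7 and 61.3 CPM in knockout replicates 1, 3 and 4. It fell from 680.6 ± 97.8 CPM to 178.7 ± 130.2 CPM (SD, n = 3), a log2 change of -1.92 (SE 0.43, edgeR adjusted p = 0.0342). In the pools the values were 442.5 and 496.3 CPM in controls against 180.6 and 157.9 CPM in knockouts. The pooled log2 change was -1.55 (SE 0.18, n = 2) with an adjusted p of 0.0794, past the threshold by DESeq2 (5.83e-11) and limma-voom (0.0303). The single-embryo call was lost without wild-type replicate 1 (adjusted p = 0.0989) or 3 (0.109), without knockout replicate 1 (0.127) or 4 (0.0735), and with the length and GC correction (-1.57, 0.0506). In the pools the log2 change of Jarid2 ran from -1.73 to -1.40 with 1 library left out. Such fits leave a single library in 1 genotype, with no spread of its own. Over all alternatives the adjusted p ran from 8.68e-14 to 0.127 in single embryos and from 5.9e-12 to 1 in pools. The deleted exons are not given in the sources used here, so counts over the whole gene can include exons outside the deletion.

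**Figure D2:**
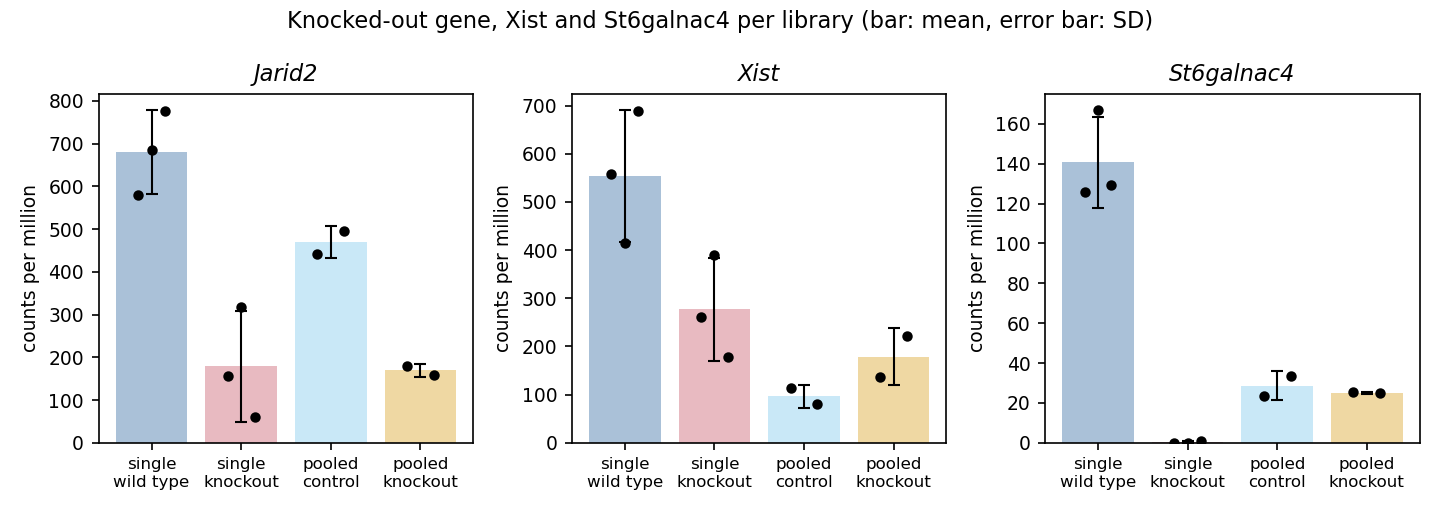
CPM of Jarid2, Xist and St6galnac4 in each library (points), with the group mean (bar) and SD (error bar). Jarid2 lies at 580.3 CPM or higher in wild-type single embryos and at 318.7 CPM or lower in all knockout libraries, while St6galnac4 is near 0 in knockout single embryos but not in knockout pools.

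The first comparison asks what differed between knockout and wild-type female single embryos. St6galnac4, a sialyltransferase gene on chromosome 2, fell from 140.6 ± 22.8 CPM to 0.4 ± 0.6 CPM (SD, n = 3; 0, 2 and 19 counts in the knockouts), a log2 change of -8.44 (SE 0.76, adjusted p = 0.00351). The glucose transporter gene Slc2a3 fell from 604.1 ± 217.3 to 117.2 ± 40.2 CPM (log2 -2.35, SE 0.32), the tight-junction gene Cldn7 from 964.0 ± 130.5 to 385.2 ± 20.9 CPM (-1.28, SE 0.17), and the collagen gene Col4a1 from 119.2 ± 32.0 to 38.1 ± 18.8 CPM (-1.63, SE 0.35). The ribosomal protein gene Rpl6 rose by 0.99 (SE 0.17), the heat shock gene Hsp90aa1 by 0.62 (SE 0.14) and Mael, a gene of the piRNA pathway, by 1.92 (SE 0.38) on the log2 scale.

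Of 13830 genes tested by edgeR, 605 passed 5%, 161 higher and 444 lower in knockouts, and 479 of them by at least 2-fold; 3131 had an unadjusted p under 0.05, where chance gives 692. In each of the 605 the groups did not overlap, as chance gives for 10% of genes. DESeq2 called 1945 genes. The count was 41 without wild-type replicate 1, 66 without knockout replicate 1 and 1316 without knockout replicate 3. Without wild-type replicate 3 or knockout replicate 4 it was 1, St6galnac4, so every other call named here needs both of those libraries.

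The largest rises by the fixed rule were of Tceal8 (5.11, SE 0.74), Tuba3a (2.26, SE 0.40), Uchl1 (2.26, SE 0.52), Prmt1 (2.24, SE 0.54), Bex1 (2.12, SE 0.45), Hspb1 (2.11, SE 0.42), Pgam2 (1.97, SE 0.48) and Mael, with adjusted p from 0.012 (Tceal8) to 0.0437 (Pgam2). Tceal8 and Bex1 are neighbours on the X chromosome, Prmt1 encodes an arginine methyltransferase and Hspb1 a small heat shock protein. Prmt1 had 28.5 ± 11.3 CPM in wild types and 126.7 ± 97.5 CPM in knockouts (SD, n = 3), so the size of its rise varied widely between knockouts. The largest falls after St6galnac4 were of the desmosomal cadherin gene Dsc2 (-4.72, SE 0.89), Dqx1 (-3.27, SE 0.78), the receptor kinase gene Tyro3 (-2.70, SE 0.62), the secreted glycoprotein gene Mfge8 (-2.67, SE 0.45), the receptor gene F2rl1 (-2.39, SE 0.43), Slc2a3 and the metalloprotease gene Adam19 (-2.34, SE 0.47). In wild types Dsc2 had 26.9 ± 28.8 CPM and Dqx1 21.8 ± 24.3 CPM (SD, n = 3), so the size of both falls rests on widely spread values.

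Of 30 junction, polarity and cavitation genes, 10 fell and 0 rose over all genes tested, and 16 fell adjusted over the list alone. The list's median log2 change was -0.71 (camera adjusted p = 2.62e-09; adjusted p = 0.138 with an estimated correlation), with Cldn6 at -1.34 (SE 0.20), F11r at -1.41 (SE 0.21) and the E-cadherin gene Cdh1 at -1.91 (SE 0.32). Of 29 trophectoderm genes, 12 fell, and 12 fell and 1 rose adjusted over the list alone. Their median was -0.89 (adjusted p = 2.98e-07; adjusted p = 0.197 with an estimated correlation). Those that fell include Slc2a3, the endocytic receptor gene Lrp2 (-1.24, SE 0.18), the prostaglandin synthase gene Ptges (-1.32, SE 0.27) and Cldn6. The transcription factor genes of the lineage did not pass, with Cdx2 at 0.23 (SE 0.32), Gata3 at -0.07 (SE 0.24) and Tead4 at 0.18 (SE 0.22). Cdh1, Ptges, Cdx2, Gata3 and Tead4 were picked after their values were seen. Of 18 primitive endoderm genes, 3 fell, the genes of the secreted matrix proteins Col4a1, Col4a2 (-2.03, SE 0.45) and Sparc (-1.54, SE 0.36), and adjusted over the list alone 5 fell and 1 rose. Their median was -0.91 (adjusted p = 0.00168; adjusted p = 0.409 with an estimated correlation), and knockout replicate 3 (0.52) lay within the library medians of the wild types (0.49 to 1.07).

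Of 24 cholesterol biosynthesis genes, 5 fell and 2 rose, and 11 fell and 3 rose adjusted over the list alone (median -0.46, adjusted p = 0.0113; adjusted p = 0.409 with an estimated correlation). Among those that fell were Cyp51 (-1.22, SE 0.22) and Ebp (-1.18, SE 0.19). The library medians of the list, as deviations from the mean of all libraries, were 0.45, 0.73 and 0.48 in wild types and -0.29, 0.50 and -0.10 in knockout replicates 1, 3 and 4. Among 19 X inactivation regulators, Lbr, the lamin B receptor gene (-1.37, SE 0.20), and Spen (-1.21, SE 0.29) fell, and 3 fell adjusted over the list alone (median -0.28, adjusted p = 0.018; adjusted p = 0.331 with an estimated correlation). The library median of these regulators was 0.22 in knockout replicate 3, within the wild-type range of 0.19 to 0.42. Of 25 genes of the Jumonji family, trithorax and H3K27 demethylases, 1 fell, Kmt2c (-1.15, SE 0.22), and 1 adjusted over the list alone (median -0.66, adjusted p = 0.00418; adjusted p = 0.409 with an estimated correlation). Nsd1 (-0.75, SE 0.23) and Kmt2a (-2.13, SE 0.67) did not pass, and the library median in knockout replicate 3 (0.24) lay within the wild-type range (0.18 to 0.85).

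Of 77 ribosomal protein genes, 9 rose, and 22 adjusted over the list alone (median 0.31, adjusted p = 6.15e-08; adjusted p = 0.409 with an estimated correlation), among them Rpl7 (0.89, SE 0.17) and Rps3a1 (1.23, SE 0.25). Of 38 germline genes 5 rose, and 6 adjusted over the list alone (median 0.84, adjusted p = 1.54e-07; adjusted p = 0.168 with an estimated correlation), with the synaptonemal complex gene Sycp3 at 1.49 (SE 0.33) and Xlr3a at 1.47 (SE 0.30). Heat shock and chaperone genes had 5 rises in 16 members by both adjustments, over all genes and adjusted over the list alone (median 0.28, adjusted p = 0.00163; adjusted p = 0.168 with an estimated correlation), among them Dnaja1 (1.05, SE 0.24). In the DNA replication and cell cycle list of 33 genes Aurka (1.09, SE 0.27) rose and Mki67 (-1.06, SE 0.22) fell, 1 each also adjusted over the list alone, and Cdc20 (0.90, SE 0.26) did not pass (median 0.39, adjusted p = 0.000213; adjusted p = 0.409 with an estimated correlation). The p53 target and the 2-cell lists passed with 0 members past 5% over all genes (edgeR; 6 and 2 members at an unadjusted p under 0.05). Their medians were 0.51 (adjusted p = 0.00531; adjusted p = 0.542 with an estimated correlation; 0 adjusted over the list alone) and 1.48 (adjusted p = 0.00762; adjusted p = 0.354 with an estimated correlation; 2 adjusted over the list alone). Pmaip1 had 1.47 (SE 0.41), Cdkn1a 0.79 (SE 0.27) and Aen 1.21 (SE 0.43) in the former, and Tdpoz2 4.64 (SE 1.25), Sp110 1.42 (SE 0.42) and Arg2 2.46 (SE 1.14) in the latter. The 2-cell list had 8 tested members here, and Tdpoz2 and Arg2 had 0.3 and 1.0 CPM in wild types. In the pools Tdpoz2 had -0.19 (SE 0.46), Arg2 -0.34 (SE 0.31) and Sp110 0.47 (SE 0.20). In all, 13 of 27 lists passed, 6 up and 7 down, 0 held with an estimated correlation, and 6 passed by fry.

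Among 18 genes imprinted through H3K27me3, the mark that PRC2 places, 2 amino acid transporter genes fell, Slc38a4 (310.4 ± 46.6 to 104.7 ± 27.9 CPM, -1.52, SE 0.24, n = 3, adjusted p = 0.015) and Slc38a1 (-1.37, SE 0.23), and 4 genes fell adjusted over the list alone. Whether these falls follow the protein class of the genes, described below, was not tested. The list's median was -0.33 (adjusted p = 0.0223; adjusted p = 0.431 with an estimated correlation). Its library medians were 0.22, 0.50 and 0.12 in wild types and -0.20, 0.36 and -0.46 in knockout replicates 1, 3 and 4, so knockout replicate 3 lay within the wild-type range. Xist, the RNA that silences the inactive X, had 553.9 ± 136.5 CPM in wild types and 276.7 ± 106.4 CPM in knockouts, -0.98 (SE 0.27, adjusted p = 0.0676), and passed by DESeq2 (adjusted p = 0.00974) and limma-voom (0.045). Over other tools, filters, scalings and left-out libraries its adjusted p ran from 0.000541 to 0.219. Sfmbt2 (-0.99, SE 0.30), Gab1 (0.08, SE 0.31), Jade1 (0.21, SE 0.21) and Smoc1 (0.46, SE 0.58) did not pass. The PRC2 genes Ezh2 (0.10, SE 0.22), Eed (0.66, SE 0.26) and Suz12 (-0.51, SE 0.23) did not pass either, and the list of 16 PRC2 subunits and cofactors had a median of 0.03 (adjusted p = 0.54). Of 34 genes imprinted through DNA methylation, Igf2r (-1.70, SE 0.25) and H13 (-1.16, SE 0.20) fell and Fkbp6 (0.77, SE 0.18) rose, adjusted over the list alone 4 fell and 1 rose, and the list did not pass (median -0.27, adjusted p = 0.364).

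Lists that did not pass also held changed genes. In the integrated stress response list, 2 genes fell, the chaperone gene Hspa5 (-1.14, SE 0.15) and Slc3a2 (-1.05, SE 0.21), and 2 rose, the asparagine synthetase gene Asns (1.71, SE 0.36) and the serine synthesis gene Psat1 (1.19, SE 0.23). Adjusted over the list alone 3 fell and 2 rose (median 0.29, adjusted p = 0.364). Among glycolysis genes the glucose transporter genes Slc2a1 (-1.82, SE 0.36) and Slc2a3 fell and Ldha (1.59, SE 0.31) rose, and adjusted over the list alone 4 fell and 1 rose (median 0.24, adjusted p = 0.883). Uqcrc2 (1.05, SE 0.26) alone passed in the list of nuclear oxidative phosphorylation genes, while Cox6a1 (-0.70, SE 0.20) and Cox7c (-0.68, SE 0.20) did not. Adjusted over the list alone 0 passed (edgeR; 11 higher and 4 lower at an unadjusted p under 0.05), and the list had a mean of 0.04 (adjusted p = 0.513). In the oocyte list Uchl1 alone passed, also adjusted over the list alone, with Dazl at 3.53 (SE 1.16) and Bpgm at 1.44 (SE 0.53), and the list's median was 0.38 (adjusted p = 0.0952). By edgeR 0 members passed in the lists of PRC1 subunits (1 at an unadjusted p under 0.05; median -0.11, mean 0.03, adjusted p = 0.651) and developmental transcription factors under Polycomb (4; median -0.28, adjusted p = 0.54). The same held for DNA and H3K9 methylation (6; median -0.28, adjusted p = 0.0952) and the Hippo pathway (2; median -0.32, adjusted p = 0.24).

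When coding genes were divided by their longest protein, a division chosen after the data were seen, 379 of 3805 genes with a hydrophobic segment (9.96%) and 54 of 7873 without one (0.686%) fell, while 15 and 137 rose (Fisher's exact p for falls 4.94e-130, over genes that are not independent replicates). The class medians were -0.49 and 0.14. The gap between classes was -0.63 (95% interval -0.68 to -0.60) in the single embryos and 0.02 (0.00 to 0.04) in the pools. Against the mean of all libraries, the gap was 0.37, 0.23 and 0.27 in wild-type single embryos, -0.22, -0.12 and -0.22 in knockout ones, and -0.14 to -0.03 in the 4 pools. Of the trophectoderm and junction genes together, 18 of 24 with a segment fell (median -1.37) and 0 of 29 without one did (median -0.15, edgeR). The imprinted lists, the X inactivation regulators and the other lists were not divided by class. Whether their falls only follow it was therefore not tested.

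X-linked genes were over-represented among the genes that rose in single embryos. Of 434 X-linked genes 17 rose (3.92%), against 143 of 12993 autosomal genes (1.1%, Fisher's exact p = 1.65e-05, adjusted over 20 chromosomes 0.000331, over genes that are not independent replicates). They include Tceal8, Bex1, Xlr3a and, picked after their values were seen, the placental regulator gene Cited1 (1.44, SE 0.33), Hprt (1.18, SE 0.24) and Rbm3 (1.04, SE 0.23). Another 10 X-linked genes fell (2.3% against 3.33%, Fisher's exact p = 0.275), among them Ebp and Magt1 (-1.34, SE 0.20). The X-linked median lay 0.20 above the autosomal one (camera p = 0.0299; p = 0.0622 with an estimated correlation). The X-linked share of counts was 3.4 ± 0.058% in wild types and 3.58 ± 0.2% in knockouts (SD, n = 3, exact permutation p = 0.2, where 3 against 3 cannot go below 0.1). The call of the median difference was lost among genes of at least 10 CPM (0.09), with the length and GC correction (0.09), and without knockout replicate 1 (0.13) or 3 (0.22). In the fixed list of 50 broadly expressed X-linked genes 3 rose and 4 fell, and adjusted over the list alone 9 rose and 6 fell. Its median (-0.01) and mean (0.11) differed in sign (camera up, adjusted p = 0.636).

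The second comparison asks the same of pools of embryos of both genotypes. Targets of p53, the transcription factor that answers DNA damage, were higher in both knockout pools: the median of 27 genes was 0.48 (adjusted p = 7.89e-14; adjusted p = 0.632 with an estimated correlation, unadjusted 0.0225). Adjusted over the list alone 10 of them rose and 0 fell, and over all genes 0 passed (edgeR; 15 at an unadjusted p under 0.05). The antiproliferative gene Btg2 had 54.7 ± 0.8 CPM in controls and 137.6 ± 28.0 CPM in knockouts (SD, n = 2; 1.23, SE 0.18, adjusted p = 0.182), the death receptor gene Fas 2.04 (SE 0.37) and Plk2 0.89 (SE 0.18). The list's library medians, as deviations from the mean of all libraries, were -0.31 and -0.23 in control pools and 0.12 and 0.26 in knockout pools. In single embryos they were -0.64, 0.48 and -0.36 in wild types and 0.30, 0.27 and 0.30 in knockouts. The single-embryo groups thus overlapped, with wild-type replicate 2 above every knockout.

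No gene of 16259 passed 5% by edgeR; 1073 had an unadjusted p under 0.05, where chance gives 813. DESeq2 called 70 genes (63 higher, 7 lower) and limma-voom 1, Jarid2. With the replicate number as a block edgeR called 39 (29 higher, 10 lower), but no label says that the numbers mark pairs. With 1 pool left out, 1 genotype has a single library and no spread of its own. Counts from such fits do not show how many genes changed. The smallest p after that of Jarid2, none of which passed, were those of Esp24 (3.22, SE 0.46), Btg2 and Plekhg1 (2.91, SE 0.46) among higher values, and of the osteopontin gene Spp1 (-1.72, SE 0.27) and Mgarp (-0.90, SE 0.17) among lower ones. Esp24 and Plekhg1 were scarce, with 0.3 and 0.6 CPM in control pools and 3.3 and 4.6 CPM in knockout pools.

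Cholesterol biosynthesis genes were lower as a list in the pools (24 genes, median -0.21, adjusted p = 0.000407; adjusted p = 0.632 with an estimated correlation), with Nsdhl at -0.62 (SE 0.20), Insig1 at -0.48 (SE 0.17) and Ebp at -0.42 (SE 0.19). So were trophectoderm genes (30 genes, median -0.20, adjusted p = 0.000423; adjusted p = 0.632 with an estimated correlation), with Ptges at -0.63 (SE 0.19), Id2 at -0.52 (SE 0.16) and the keratin gene Krt18 at -0.51 (SE 0.21). The library medians of the groups overlapped in both lists: -0.58 and -0.24 in control pools against -0.65 and -0.52 in knockout pools for cholesterol genes, and -0.44 and -0.00 against -0.42 and -0.13 for trophectoderm genes. In both lists 0 members passed over all genes or adjusted over the list alone (edgeR; 2 and 4 at an unadjusted p under 0.05). Higher as lists were the 22 transcripts of the 2-cell stage (median 0.38, adjusted p = 0.0074; adjusted p = 0.632 with an estimated correlation), 19 genes imprinted through H3K27me3 (0.15, 0.0237; adjusted p = 0.632 with an estimated correlation) and 50 developmental transcription factors under Polycomb (0.32, 0.0463; adjusted p = 0.779 with an estimated correlation). In the imprinted list the library medians overlapped, with -0.31 and -0.08 in control pools and -0.34 and 0.10 in knockout pools 1 and 2, and in the developmental list they were -0.25 and -0.14 against -0.14 and 0.13. Of these, 0 passed over all genes (5, 4 and 4 at an unadjusted p under 0.05), and 1 rose adjusted over the list alone, in the imprinted list. Their members with the smallest p were Zfp750 (1.93, SE 0.51), BB287469 (2.7, SE 0.80) and Obox6 (0.65, SE 0.23); Otx2 (0.95, SE 0.23), Xist and Bmp7 (1.31, SE 0.45); and Otx2, Foxc2 (1.71, SE 0.53) and Gata4 (1.56, SE 0.51). Some of these were scarce: Foxc2, Gata4 and Bmp7 had 0.6, 0.5 and 0.8 CPM in control pools and 2.0, 1.7 and 2.0 CPM in knockout pools. Otx2 had 9.8 and 20.3 CPM. In all, 6 of 29 lists passed, 4 up and 2 down, 0 held with an estimated correlation and 0 passed by fry. Without knockout replicate 1 the count was 11. Lists that passed in single embryos and not in pools include junctions (-0.07, adjusted p = 0.116), ribosomal proteins (0.09, 0.0715), germline genes (0.19, 0.116), DNA replication (-0.05, 0.0796), primitive endoderm (0.22, 0.168) and heat shock (median -0.05, mean 0.22, adjusted p = 0.41). The difference between the sets is a separate test.

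Xist had 96.1 ± 23.5 CPM in control pools and 178.7 ± 59.3 CPM in knockout pools (SD, n = 2, log2 change 0.79, SE 0.24, edgeR adjusted p = 0.584). It passed with no filter on low counts (edgeR adjusted p = 0.0127) and not by DESeq2 (0.194) or limma-voom (0.65). With 1 pool left out, which leaves a single library in 1 genotype, its log2 change ran from 0.48 to 1.09. Slc38a4 (-0.36, SE 0.21), Sfmbt2 (0.15, SE 0.24), Gab1 (0.03, SE 0.18), Jade1 (0.09, SE 0.20), Smoc1 (0.15, SE 0.29), Ezh2 (0.08, SE 0.17), Eed (-0.30, SE 0.20) and Suz12 (0.09, SE 0.16) did not pass. The median of 522 X-linked genes lay 0.03 above the autosomal one and did not pass by camera. That difference was -0.02 without control replicate 2, -0.05 without knockout replicate 1, and 0.08 without knockout replicate 2, each with a single library in 1 genotype. Their share of counts was 3.16 ± 0.2% in controls and 3.15 ± 0.27% in knockouts (SD, n = 2, exact permutation p = 1, smallest possible 0.333).

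**Figure D3:**
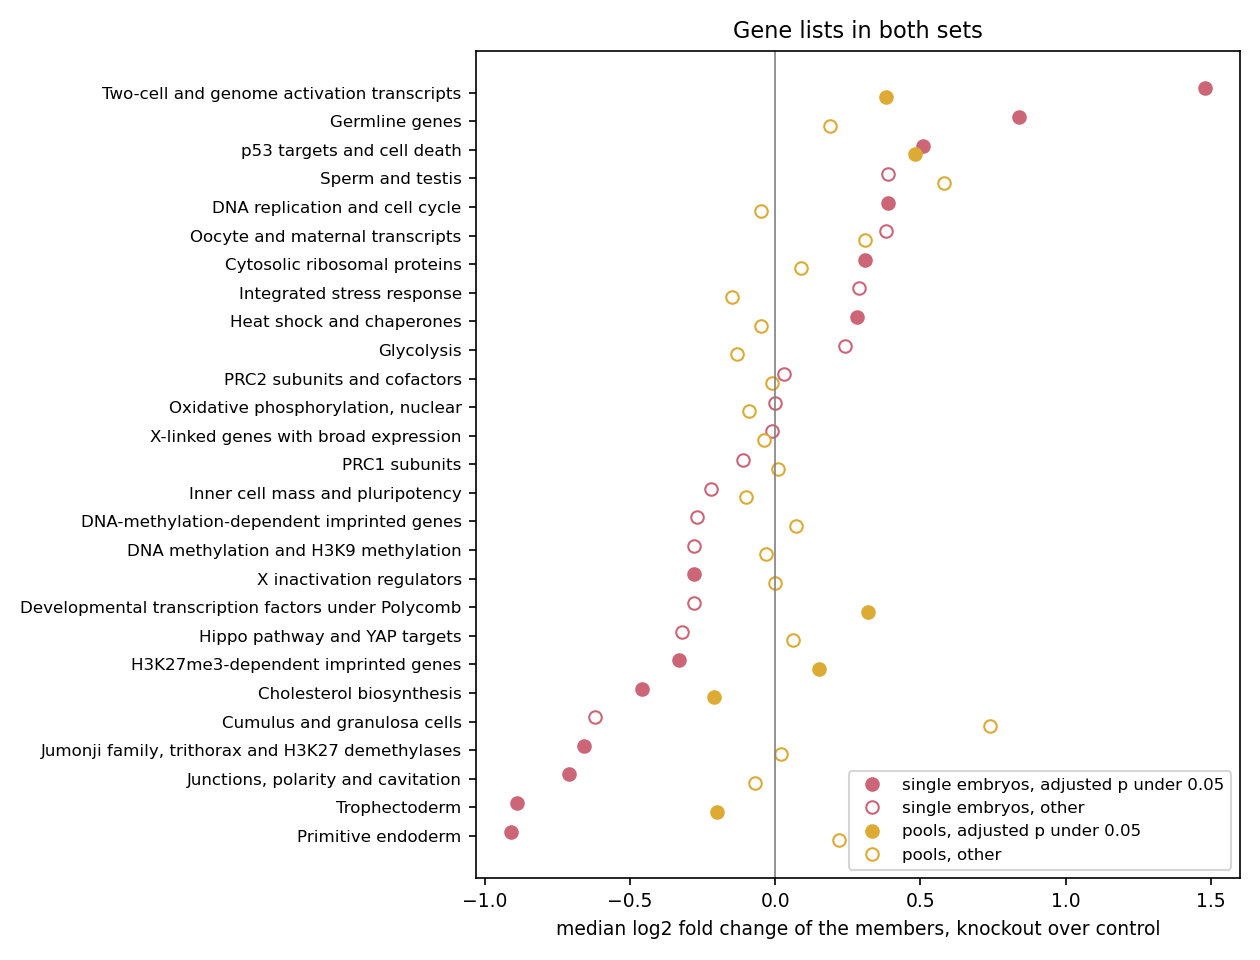
Median log2 change (knockout over control) of each gene list in single embryos and pools; filled points have a camera adjusted p under 0.05 with the preset correlation. Trophectoderm, cholesterol, p53 and 2-cell lists pass in both sets in the same direction, and H3K27me3-imprinted genes pass at -0.33 in single embryos and 0.15 in pools, where knockout pool 1 lay below both controls. The 2-cell list had 8 tested members in single embryos and 22 in pools. With an estimated correlation 0 lists pass in either set (adjusted p = 0.632 for each of these 5 lists in the pools).

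The third comparison asks whether the knockout effect was shared by the sets. Over 13677 genes tested in both, log2 changes had a Pearson correlation of -5.95e-05 (Spearman -0.0741), across genes, which are not independent replicates, and 44.1% had the same sign. The 444 genes that fell in single embryos had a median of 0.13 in that direction in the pools (95% interval 0.09 to 0.16) against 1.28 in the single embryos, and 306 (68.9%) were lower in knockout pools. The 161 that rose had a pooled median of -0.11 (95% interval -0.16 to -0.08), against their single-embryo direction, and 39 (24.2%) were higher in knockout pools. The fit of the difference shared its estimate of spread over all 10 libraries (biological coefficient of variation 0.485). The pools fitted alone had 0.234, so their part was tested with a wider spread than their own. By the test of the difference itself, 1 gene of 15878 passed, St6galnac4 (single minus pooled -8.15, SE 0.89, adjusted p = 0.00889), while 2326 had an unadjusted p under 0.05 and DESeq2 called 436. It did not pass without control pool 1 or 2 or wild-type replicate 2 or 3 (0 genes each), and 2 genes passed without knockout single embryo 1, St6galnac4 and Mfge8. The p53 list had a median difference of 0.02 between the sets and a mean of -0.24 (camera adjusted p = 0.98). The cholesterol list had a median difference of -0.17 (camera adjusted p = 0.631). A difference that did not pass does not show equal effects.

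**Figure D4:**
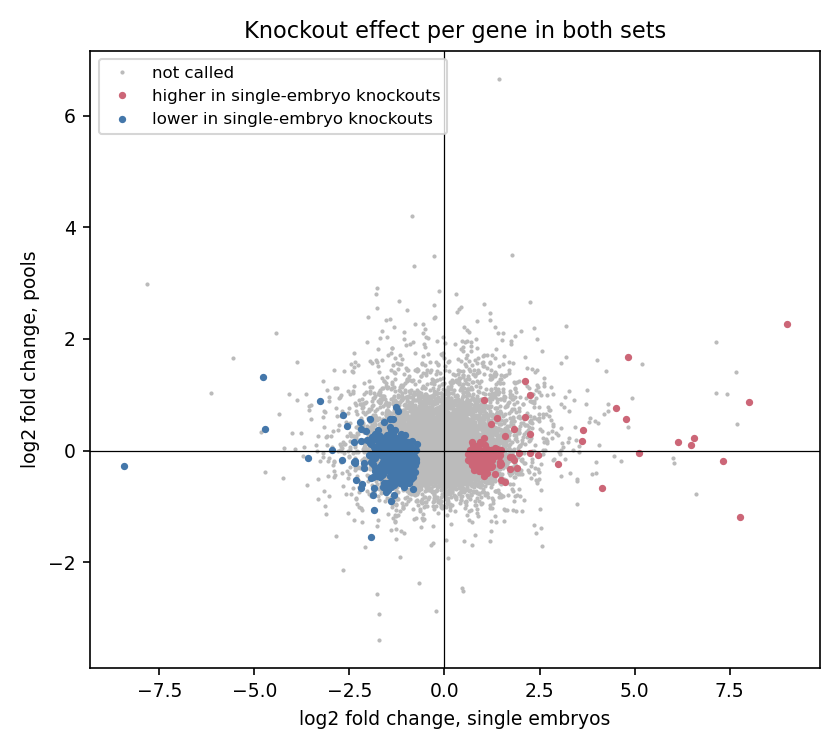
Log2 change (knockout over control) of each gene in single embryos against that in pools, with genes called in single embryos coloured. The cloud has a correlation of -5.95e-05, and the called genes spread along the single-embryo axis with pooled medians near 0.

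Averaged over both sets, the disulfide isomerase gene P4hb fell by 0.84 (SE 0.12), Pdia4 by 0.81 (SE 0.13), Calr by 0.73 (SE 0.12), Hspa5 by 0.65 (SE 0.11) and Surf4 by 0.79 (SE 0.13), next to the junction genes Cldn7 (-0.86, SE 0.15) and F11r (-0.90, SE 0.16); these examples were picked after their values were seen. In all 40 of 15878 genes passed, 34 lower, with Jarid2 (-1.72, SE 0.32, adjusted p = 0.0468) and St6galnac4 (-4.34, SE 0.45), and 6 higher: Cryab (0.99, SE 0.17), Pdk3 (3.61, SE 0.64), S100a6 (1.57, SE 0.28), Tceal8 (2.55, SE 0.44), Tex13 and Tuba3a (1.64, SE 0.28). The average can rest on 1 set: in single embryos and pools Tceal8 had 5.11 and -0.04, Pdk3 7.32 and -0.19, St6galnac4 -8.44 and -0.27, and Hspa5 -1.14 and -0.19, against 1.04 and 0.90 for Cryab. The count was 26 without control pool 1, 1 without control pool 2, 0 without either knockout pool (edgeR; 1813 genes with an unadjusted p under 0.05 over all libraries, DESeq2 484, limma-voom 141), 1 without wild-type replicate 1 or 3 or knockout single embryo 4, 2 without knockout single embryo 1, 130 without wild-type replicate 2 and 81 without knockout single embryo 3.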

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

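The 2 tests on left-out wild-type libraries, the tests of equal Jarid2 effects among called genes and among X-linked genes, the test of trophectoderm and junction genes by protein class, and the test of the whole X chromosome were chosen after the results they test had been seen. St6galnac4 and the 11 lists of the next paragraph stand here because a test of the difference between the knockout effects in single embryos and in pools passed, and the patterns weighed after them were chosen for follow-up without such a call. Groups of 2 or 3 libraries are too small for a test of outlying samples.

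St6galnac4 had a knockout effect that differed between single embryos and pools (single minus pooled -8.15, SE 0.89, adjusted p = 0.00889). By camera 11 of 29 lists differed between the sets, 5 up and 6 down, and 0 of them with an estimated correlation (adjusted p 0.442 to 0.602). Single minus pooled, the median difference was -0.97 for primitive endoderm genes (adjusted p = 0.000722), -0.63 for junction, polarity and cavitation genes (1.27e-05), -0.63 for the Jumonji and trithorax list (0.00985), -0.62 for genes imprinted through H3K27me3 (0.00594), -0.39 for X inactivation regulators (0.0368) and -0.26 for trophectoderm genes (0.0113). It was 1.51 for transcripts of the 2-cell stage (0.00863), 0.81 for germline genes (1.01e-05), 0.46 for DNA replication and cell cycle genes (9.38e-05), 0.28 for heat shock genes (0.00863) and 0.23 for ribosomal protein genes (0.000545).

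The 605 genes called in single embryos had a pooled median of 0.05 in the same direction (0.02 to 0.08) against 1.22 in single embryos. The 444 that fell had 0.13 in their direction (0.09 to 0.16), while the 161 that rose had -0.11 (-0.16 to -0.08), against theirs. These medians lie below what an equal effect of Jarid2 loss in both sets predicts. The genes were chosen by their single-embryo values, however, which inflates the 1.22 by an amount not measured. Length and GC bias does not account for most of the 605 calls, since 416 of them stayed called after the smooth, which called 558 in all. Of these 558, 100 were higher and 458 lower, so the rises were fewer than the 161 before. Across genes, log2 change and transcript length had a Spearman correlation of -0.265 before the smooth and -0.0081 after it. When each wild-type library was left out of the choice of genes, pooled controls, which carry Jarid2, differed from it in the knockout direction by 0.93, 0.83 and 0.90 of the knockout difference (the other wild types by 0.07, -0.42 and -0.18 on the log2 scale), and by 0.52 to 1.15 of it when the differences shared no wild-type library. This is what wild-type single embryos that stand apart for a reason other than Jarid2 would give, and a processing batch, a stage difference, or an effect of Jarid2 that differs between single embryos and pools may each lie behind it, since the labels give neither batch nor exact stage. Of the 10 splits of the 6 libraries, 1 (the real one, 605 genes; highest other 0) called as many genes and 1 (the real one, 13; highest other 9) passed as many lists, which is too few splits for a share under 0.05.

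The knockout over wild-type change of messages with a hydrophobic segment lay 0.63 below that of other messages, with the wild types (0.23 to 0.37) apart from knockouts and pools (-0.22 to -0.03). The gap stayed at -0.52 (-0.55 to -0.48) after the length and GC smooth and was 0.02 in the pools, so neither length and GC bias nor an equal effect of Jarid2 loss accounts for it. Trophectoderm and junction members without a segment had a median of -0.15 (-0.36 to 0.07), against 0.14 for all such genes. Members with a segment had -1.37 (-1.70 to -1.22), against -0.49 for all genes with a segment. Both medians lay below that of their class, which argues against these genes having fallen only as members of it. The thresholds set for that test decided neither way, and the intervals run over genes and not over embryos. Of the 10 splits, 1 (the real one, 0.63; highest other 0.31) gave as large a gap, which is too few splits for a share under 0.05. A loss of membrane-bound messages during the lysis of some libraries could give such a gap, as could a change in the secretory pathway, and neither was tested.

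X-linked genes stayed over-represented among genes higher in knockout single embryos after the length and GC smooth (9 X-linked, 90 autosomal, Fisher's exact p = 0.0047, over genes that are not independent replicates). In the pools the 17 X-linked genes called higher had a median of -0.11 (-0.24 to 0.09) against 1.39 in single embryos, below what an equal effect predicts. They too were chosen by their single-embryo values, which inflates the 1.39 by an amount not measured. A rise along the whole X chromosome stays open: X-linked genes that were not called lay 0.17 above autosomal ones (0.06 to 0.23), and 0.06 (-0.02 to 0.14) after the smooth. Of the 10 splits, 1 (the real one, 0.198; highest other 0.1) gave as large a median difference, which is too few splits for a share under 0.05. The pools hold embryos with Y-linked messages and the single embryos are female, so sex may also part the sets, and no test here separates it (0.17 remains open).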

How the results depend on the processing

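The length and GC correction was the one alternative chosen after the data were seen. Changed genes in single embryos numbered 605 and stayed within 1.5 times of that under 8 alternatives, with the split between higher and lower going from 161 and 444 to 301 and 423 under upper quartile scaling. DESeq2 called 1945, no filter on low counts 1715, a filter of at least 10 CPM 1243 and all 10 samples fitted together 1667. Leaving out 1 library gave 1 to 1316. Left-out libraries leave fewer samples, but that does not account for the rise to 1316 without knockout replicate 3. The cause was not tested. In the pools 0 passed by edgeR (1073 at an unadjusted p under 0.05), against 70 by DESeq2, 1 by limma-voom and 170 with no filter, and 25 to 379 with 1 library left out, where a lone library is assumed to vary like the other group; the cause was not tested. The difference between sets gave 1 gene, 436 by DESeq2, 548 with no filter and 0 to 2 with 1 library left out. The average gave 40, but 1 with upper quartile scaling, 484 by DESeq2, 141 by limma-voom, 579 with no filter, 95 at 10 CPM, 14 with a 2-fold minimum, 92 with the length and GC correction and 0 to 130 with 1 library left out; the cause was not tested.

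Passing lists numbered 13 in single embryos and 6 in pools, 0 and 0 with an estimated correlation, 6 and 0 by fry, and 12 to 14 and 5 to 11 with 1 library left out. With the length and GC correction 10 lists passed in single embryos, 9 of them among the 13, and 8 in pools, 5 of them among the 6. The X-linked difference was 0.20 in single embryos, 0.09 at 10 CPM, 0.20 and not past the threshold with an estimated correlation, 0.09 with the length and GC correction, and 0.13 to 0.24 with 1 library left out. In pools it was 0.03, -0.01 at 10 CPM and -0.05 to 0.09 with 1 library left out. The correlation between the sets was -5.95e-05, 0.159 among called genes and -0.12 to 0.15 with 1 library left out. The cause was not tested.

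Reversed values belong to genes that did not pass. With the length and GC correction Ezh2 had -0.13 in single embryos and Gab1 -0.01 in pools. With 1 library left out the ranges in single embryos were -0.01 to 0.28 for Ezh2, -0.21 to 0.32 for Gab1 and -0.09 to 0.99 for Smoc1. In pools they were -0.05 to 0.18 for Ezh2, -0.09 to 0.14 for Gab1, -0.21 to 0.43 for Sfmbt2, -0.14 to 0.34 for Jade1 and -0.20 to 0.43 for Smoc1; the cause was not tested. Of 1289 values of named genes in single embryos 973 kept their direction and their side of the threshold, 65 gained a call and 246 lost one, and of 471 in pools, where no named gene had a call, 401 kept their direction and stayed without one and 61 gained one. Of 169 values of lists in single embryos 138 kept the call and 31 lost it, and of 66 in pools 42 kept it and 24 lost it.

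The replicate numbers were not treated as pairing: deviations of same-numbered single embryos correlated at -0.01 and -0.08, while in the pools they correlated at 0.32, with only 2 numbers, so whether the pools are paired stays open. With the number as a block the counts were 187 in single embryos (116 of the 605 kept), 39 in pools (Jarid2 among them, adjusted p = 0.00322), 0 for the difference and 0 for the average, 13 and 8 lists passed, and the correlation between the sets was 0.0851.

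In simulated counts edgeR recovered 28 of 100 genes changed by 2-fold in the single-embryo design and 79 of 100 in the pooled one, all drawn above a mean of 10 CPM. The designs differ in depth, spread between libraries (biological coefficient of variation 0.509 and 0.234) and number of libraries, and depth alone was not varied.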

Other observations

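The test of pooled libraries numbered 1 and 2 was chosen after the values had been seen. Over all genes 0 pluripotency genes passed in either set by edgeR (7 and 5 at an unadjusted p under 0.05), and adjusted over the list alone 1 fell in the pools, Spp1 (-1.72, SE 0.27). Nanog had -0.14 (SE 0.25) in single embryos and -0.51 (SE 0.16) in pools, Pou5f1 0.75 (SE 0.36) and -0.35 (SE 0.17), and Sox2 -0.79 (SE 0.56) and -0.41 (SE 0.31). The list of inner cell mass genes had medians of -0.22 (adjusted p = 0.636) and -0.10 (adjusted p = 0.116).

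Averaged over both sets, 12 of 29 lists passed by camera, 6 up and 6 down, 0 with an estimated correlation and 5 by fry. Ribosomal protein genes had a median of 0.20 (adjusted p = 7.44e-12; adjusted p = 0.265 with an estimated correlation), germline genes 0.50 (1.8e-08; adjusted p = 0.121 with an estimated correlation) and p53 targets 0.45 (6.06e-06; adjusted p = 0.266 with an estimated correlation). Transcripts of the 2-cell stage had 1.35 (8.16e-06; adjusted p = 0.121 with an estimated correlation), trophectoderm genes -0.38 (1.82e-08; adjusted p = 0.171 with an estimated correlation) and cholesterol biosynthesis genes -0.39 (7.34e-05; adjusted p = 0.265 with an estimated correlation).

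The lists of markers of other cells did not pass. In single embryos 4 cumulus and granulosa genes had a median of -0.62 (adjusted p = 0.54) and 3 sperm and testis genes 0.39 (adjusted p = 0.364). In pools cumulus genes had 0.74 (adjusted p = 0.116; adjusted over the list alone 1 rose, Serpine2, 0.74, SE 0.16), sperm genes 0.58 (0.116), blood genes 0.23 (0.882) and Y-linked genes -0.13 (0.769). Y-linked genes held 8.7 to 18.9 CPM in the single embryos and 136.7 to 145.9 CPM in the pools. Of the Y-linked genes named in the list, Ddx3y, Eif2s3y and Kdm5d had 0 counts in each of the 6 single embryos and Uty had 3 counts in 1 of them. The other pooled lists that did not pass were PRC2 (-0.01, adjusted p = 0.715), PRC1 (0.01, 0.653), genes imprinted through DNA methylation (0.07, 0.355), X inactivation regulators (median -0.00, mean 0.06, 0.895), broadly expressed X-linked genes (-0.04, 0.41) and oocyte transcripts (0.31, 0.0715). So were the integrated stress response (-0.15, adjusted p = 0.217), glycolysis (-0.13, 0.268), oxidative phosphorylation (-0.09, 0.0521), DNA and H3K9 methylation (-0.03, 0.507), the Jumonji list (0.02, 0.895) and the Hippo pathway (0.06, 0.578).

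A hypothesis was that what separates the single-embryo groups also separates pools of 1 genotype. Pooled replicate 1 minus 2, in the knockout direction, the 605 genes had a median of 0.35 in controls (0.33 to 0.37; 95.5% of genes) and 0.26 in knockouts (0.24 to 0.29; 82.3%). Each difference sets 1 pool against 1 pool, and its interval runs over genes that vary together, so the shared sign is weak support and the hypothesis stays open. What the replicate numbers mark is not given in the sources used here. Of 60 splits within the sets, 2 called as many genes on average, the real one (40) and 1 other (429), which sets pooled replicates 2 with wild types against pooled replicates 1 with knockouts. With every library of one single-embryo group required to be under 1 CPM and every library of the other at 10 CPM or more, 0 genes were counted (St6galnac4 had 1.1 CPM in knockout replicate 4), and the highest count among the other splits was 1.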
